A study of Arabidopsis thaliana with 4 samples.

How the data were processed

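PRR9 binding was measured in 4 libraries, 1 per group, from whole seedlings: input and immunoprecipitated DNA of the HA-PRR9 line and of the prr9-1 control, with an antibody against the HA tag per the labels. The PRR9 list was made from the input and immunoprecipitated library of the HA-PRR9 line, per the description sheet deposited by the authors, which does not name the control line for it. The lists for PRR7, PRR5 and TOC1 were made by the authors from reads of other series, per the same sheet. No replicates were pooled or compared, since each list rests on single libraries as far as the sheet says.

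Reads were quality-trimmed by the authors with the Fastx Toolkit (quality 20, minimum length 30), aligned with Bowtie keeping reads with at most 1 alignment, and peaks were called with MACS2 in broad mode on TAIR10, per the description sheet. The submitters' processing notes name Bowtie and MACS2. Tool versions are not given in the sources used here. Keeping uniquely aligned reads lowers coverage of repeated DNA. Each deposited list gave peak positions, a 1 bp summit and a score. The peak score is the authors' own per-peak value, deposited with no stated unit, and it was used only to rank, filter and describe peaks within a list. The deposited scores all exceeded 1.30, which is 0.05 on the negative log10 scale. Scores in the peak and summit lists were equal for each peak, and each summit lay inside its peak.

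The authors' annotated tables named 1 gene for each nuclear peak. They state the rule as nearest start for PRR9, PRR5 and TOC1 and nearest location for PRR7, so the same site can be given different genes. The deposited distances run from the peak start, so distances here were computed from the summit to the start of the named gene, counted negative upstream. Positions are 1-based. Exons, introns and untranslated regions were not assigned, since no gene models were used here. Symbols came from a RefSeq gene table of assembly TAIR10.1, used for names, gene types and neighbours only. Of 6676 distinct loci named, 6544 matched it.

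Peaks were called overlapping from 1 bp. Overlap was tested against 10000 uniform placements of the shorter list within its chromosomes, one-sided, with each chromosome taken to end at the last position in the deposited lists and annotated tables; the plan gave that placement as the fallback where no gene models were at hand. Shared genes and gene lists were tested with two-sided Fisher's exact tests against 27444 nuclear protein-coding genes, and a gene counted as named where the deposited table named it, also the planned fallback. The 13 gene lists were fixed before the data were examined. Score differences were tested with 100000 permutations, two-sided. Benjamini-Hochberg adjustment was made over each family. The code ran on Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

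The placement test was tested on simulated data with 165 peaks against a simulated list as long as that of PRR5. Both simulated lists were placed uniformly, so these runs do not cover the clustering of real peaks near gene starts. It counted 20 planted overlaps exactly in 200 of 200 runs, and 13 of 200 runs without planted overlaps passed 0.05. The score test on 279 peaks passed 0.05 in 9 of 200 runs with no shift and in 200 of 200 with a shift of 3. Smaller shifts were not simulated.

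The genes named in the text follow a rule fixed before the data were examined: the core clock members, the genes of the 10 strongest peaks of each list, the 15 genes named in all 4 lists with the strongest PRR9 peaks, the 5 strongest genes named only in PRR9, and at most 5 PRR9-named members of each other gene list, or members named in the longest list where PRR9 named none. AT1G22767, AT2G40081, AT3G18779, the loci with several PRR9 peaks, CPC, and the TOC1 peaks at PIF4 and PIF5 were singled out after their values were seen. So were genes named only in the additional or other observations. Alternatives covered the overlap rule, list length, score, window, gene assignment, placement, and leaving out chloroplast peaks and peaks in the 2 Mb window of each nuclear chromosome with the fewest protein-coding genes. A motif search at summits was planned and not run, since no genome sequence was used here.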

Results

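Chromatin immunoprecipitation followed by sequencing was used to map where PRR9, a pseudo-response regulator of the Arabidopsis circadian clock, sits on the genome. Whole seedlings grown in 12 h light and 12 h dark were collected at zeitgeber time 4, that is 4 h after lights on, at 2 weeks of age. There were 4 libraries, 1 in each group: input and immunoprecipitated DNA of a prr9-1 mutant line that carries HA-tagged PRR9 under its own promoter, and input and immunoprecipitated DNA of the prr9-1 control without the tagged protein. Both lines also carry a CCR2::LUC luciferase reporter transgene. The values used here were the deposited peak lists, not reads, so read depth per library was not examined. Lists made by the authors for the related proteins PRR7, PRR5 and TOC1 were deposited beside the PRR9 list. Per the deposited description sheet, those plants were collected at zeitgeber times 11 to 12, 12 and 15 h. The PRR5 plants were 18 days old. Each protein has 1 list and no replicate list, so the intervals given here are exact 95% Clopper-Pearson intervals that cover counting error only. Protein and collection time changed together between lists.

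PRR9 and PRR7 peaks lay mostly upstream of genes, whereas TOC1 peaks lay most often inside genes. The PRR9 list held 279 peaks, of which 165 were on the 5 nuclear chromosomes and 114 on the chloroplast chromosome. The PRR7, PRR5 and TOC1 lists held 1344, 9036 and 484 peaks, with 0, 0 and 7 of them on the chloroplast chromosome. Of the nuclear PRR9 peaks, 68.5% (interval 60.8 to 75.5) lay upstream of the gene the authors named and 6.06% (2.94 to 10.9) inside it. For PRR7 the shares were 69.3% (66.7 to 71.7) and 10.6% (8.97 to 12.3). For PRR5 they were 44.4% (43.4 to 45.5) and 22.5% (21.7 to 23.4). For TOC1 they were 36.7% (32.4 to 41.2) and 47.0% (42.4 to 51.6). When upstream and start-overlapping peaks were set against peaks inside genes, PRR9 differed from TOC1 by an odds ratio of 16.2 (two-sided Fisher's exact test, p = 6.47e-27, adjusted p = 9.70e-27 over 6 pairs). PRR9 and PRR7 did not differ past the threshold (odds ratio 1.81, Fisher's exact p = 0.0941, adjusted p = 0.0941). The median summit lay at -285 bp from the transcription start site for PRR9, -194 bp for PRR7, -75 bp for PRR5 and 323 bp for TOC1. Between 1000 bp upstream and 200 bp downstream of the start lay 87 of 165 PRR9 summits (52.7%, interval 44.8 to 60.5), 59.8% (57.1 to 62.5) of PRR7, 52.6% (51.5 to 53.6) of PRR5 and 32.7% (28.5 to 37.1) of TOC1 summits.

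**Figure D1:**
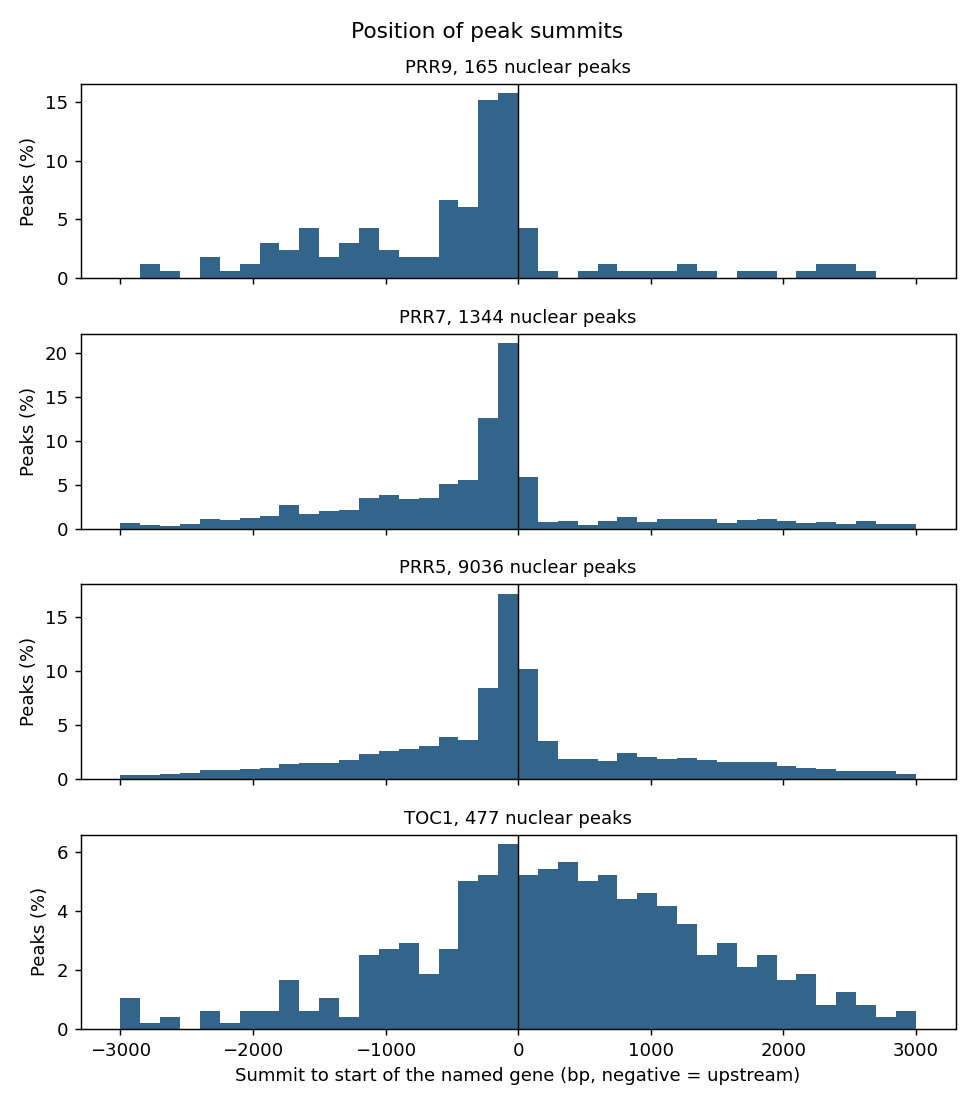
Histograms of the distance from each nuclear peak summit to the start of the gene named by the authors, in bp (negative is upstream), as percent of the nuclear peaks of each list in bins of equal width. Summits farther than 3000 bp are not drawn; the median moves from -285 bp for PRR9 to 323 bp for TOC1.

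Most nuclear PRR9 peaks coincided with PRR7 and PRR5 peaks, and fewer with TOC1 peaks. These included the promoters of LHY and CCA1, the morning-phased MYB transcription factors of the clock, where all 4 lists held a peak. PRR7 peaks overlapped 119 of the 165 nuclear PRR9 peaks (72.1%, interval 64.6 to 78.8), PRR5 peaks 125 (75.8%, 68.5 to 82.1) and TOC1 peaks 29 (17.6%, 12.1 to 24.3). Of these 165 peaks, 26 were overlapped by all 3 other lists, 90 by 2, 15 by 1 and 34 (20.6%, 14.7 to 27.6) by none. With the chloroplast peaks counted, the shares of the 279 peaks were 42.7% for PRR7, 44.8% for PRR5 and 12.5% for TOC1, against 0.216%, 2.01% and 0.978% expected from uniform random placement. Placement at starts of genes named in the deposited tables, added after seeing the data, raised the expected shares to 1.95%, 13.4% and 1.28%. The PRR5 share was then 3.36 times its expectation rather than 22.3 times. The PRR5 list itself named 6572 of the 6676 loci used, which raises the PRR5 expectation by construction. That fall therefore does not measure preference for gene starts alone. Without chloroplast and gene-poor peaks, uniform placement gave 0.376%, 3.43% and 0.128%, and the observed shares were 208, 23.9 and 150 times these for PRR7, PRR5 and TOC1, against 12.8 times for TOC1 with them. Each one-sided random-placement permutation test gave p = 0.0001 (adjusted p = 0.0001 over 6 pairs), the smallest that 10000 placements can give. Among the PRR5 peaks alone, PRR7 peaks overlapped 92.2% of the 128 that PRR9 peaks also overlapped and 12.3% of the remaining 8908 (odds ratio 83.8, two-sided Fisher's exact p = 6.84e-92, adjusted p = 2.05e-91 over 3 pairs). Cutting all lists to their 279 strongest peaks gave shares of 29.4% for PRR7, 15.8% for PRR5 and 7.89% for TOC1. Requiring overlap of at least 50% of the PRR9 peak gave a TOC1 share of 2.51% of the 279 peaks. Peak width alone can cause that drop, since the median width was 82 bp for TOC1 and 198 bp for PRR9. With summits within 250 bp the TOC1 share was 11.8%.

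The PRR7 list was almost wholly contained in the PRR5 list. PRR5 peaks overlapped 1289 of 1344 PRR7 peaks (95.9%, interval 94.7 to 96.9) and 356 of 484 TOC1 peaks (73.6%, 69.4 to 77.4). PRR7 peaks overlapped 123 TOC1 peaks (25.4%, 21.6 to 29.5). Uniform placement gave 2.65%, 2.62% and 0.254%. Placement at starts of named genes, most of them named by PRR5, gave 19.8%, 12.8% and 1.21%. Under both, each permutation p was 0.0001 (adjusted p = 0.0001), the smallest possible. PRR5 peaks covered 1.79% of the nuclear chromosomes, against 0.131% for PRR7, 0.0472% for TOC1 and 0.0312% for PRR9. With the 279 strongest peaks of each list the 3 shares fell to 30.1%, 10.4% and 11.5%.

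**Figure D2:**
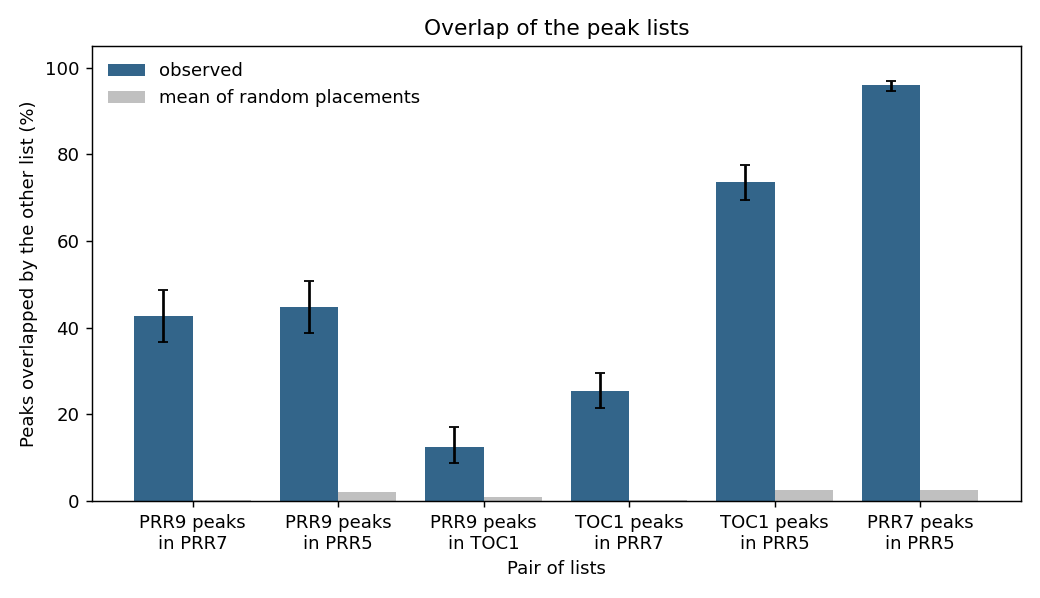
Percent of the peaks of the first list overlapped by at least 1 bp by the second (blue bars, whiskers are exact 95% intervals) and the mean of 10000 random placements (grey bars), for 6 pairs of lists. Observed shares run from 12.5% to 95.9%, and the placement means from 0.216% to 2.65%.

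The genes named for the peaks were shared in the same way. The PRR9 list named 125 nuclear protein-coding genes, of which 103 were also named for PRR7, 106 for PRR5 and 31 for TOC1, whose lists named 1076, 6066 and 321. The odds ratios were 127, 19.99 and 30.7 against a background of 27444 genes, and the largest of the 3 two-sided Fisher's exact p-values was 2.34e-32 (adjusted p = 2.34e-32 over 6 pairs). With summits from 500 bp upstream to 200 bp downstream of the start the odds ratios were 273, 42.0 and 72.8. With the 279 strongest peaks of each list they were 230, 58.2 and 22.5, from 74, 37 and 16 shared genes, so PRR5 then ranked above TOC1. The PRR7 and PRR5 lists shared 1031 genes (odds ratio 97.1), TOC1 and PRR5 289 (33.4), and TOC1 and PRR7 131 (19.1). All 4 lists named 28 genes, against 0.0127 expected from independent lists and at most 1 in 10000 random draws (permutation p = 0.0001, the smallest possible). The count fell to 6 with the stronger 50% of each list and to 6 with the 279 strongest peaks of each. Of the 28, the 15 with the strongest PRR9 peaks were LHY, CCA1, the B-box genes BBX28 and BBX29, the cold-response regulator CBF2, PRR5, BTI1, RPT2, AT1G19490, AT1G68440, the light-stress gene ELIP1, RHA2A, AT4G21930, the sigma factor gene SIG4 and HB-12. Their PRR9 scores ran from 95.8 at LHY to 7.62 at HB-12. Their TOC1 scores ran from 9.89 at AT4G21930 to 1.35 at HB-12, the lowest score of that list. LHY had 9.10, CCA1 2.29 and CBF2 1.66, against a median of 3.95 over the nuclear TOC1 peaks. PRR9 alone named 12 genes, led by AT3G61690 (score 17.0), AT1G40104 (14.0), AT3G61680 (13.7), AT3G23470 (13.4) and SCRL19 (11.003). AT1G40104 lies in a gene-poor window. Of the 12, 1 (CPC) had a PRR9 peak that PRR7 and PRR5 peaks named for other genes also overlapped.

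Clock genes were named far more often than genes at large in every list. Highly transcribed genes, a check given below, also passed in the PRR7, PRR5 and TOC1 lists. Of 32 core clock genes fixed before the data were examined, PRR9 peaks named 12 (37.5%, interval 21.1 to 56.3), PRR7 16, PRR5 19 and TOC1 5. The odds ratios were 145, 24.9, 5.16 and 15.9, with adjusted p-values from two-sided Fisher's exact tests of 5.04e-19, 1.61e-13, 2.96e-05 and 0.000122 over 52 pairs of gene and peak lists. With summits from 500 bp upstream to 200 bp downstream of the start they were 281, 43.3, 10.3 and 39.8. With the 279 strongest peaks of each list they were 145, 80.2, 17.0 and 20.6, and PRR5 then named 4 clock genes. CCA1, LHY, PRR5 and RVE3 were named in all 4 lists. RVE1, RVE2, RVE7, LNK2 and LNK4 were named in PRR9, PRR7 and PRR5. RVE8 and LNK1 were named in PRR9 and PRR7, and LNK3 in PRR9 and TOC1. PRR7, GI, BOA and RVE4 were named in PRR7 and PRR5. LUX was named for PRR7 alone, and TOC1, ZTL, CHE, RVE5, COR27 and COR28 for PRR5 alone. No list named PRR9, PRR3, ELF3, ELF4, FKF1, LKP2, RVE6, LWD1 or LWD2. The assignment moved some sites to a neighbour. The peaks nearest PRR9 were named for the short locus AT2G46787 in all 4 lists. The PRR9 peak named for LNK3 was overlapped by PRR7 and PRR5 peaks named for other genes. The PRR7 peak named for LUX, and the PRR9 and PRR7 peaks named for RVE8 and LNK1, were likewise overlapped by PRR5 peaks named for other genes. When genes were assigned jointly to overlapping peaks, an alternative added after seeing the data, PRR5 had 23 clock genes rather than 19 and its odds ratio was 8.99. The PRR7-list peak named for PRR7 lay inside the gene, 2104 bp from its start. The PRR5-list peak at the PRR7 start was overlapped by PRR7-list and TOC1-list peaks named for other loci, and joint assignment placed PRR7 in these 3 lists. The 3 PRR9-list peaks named for CDL1 lay between 638592 and 639604 on chromosome 5. That is close to the PRR7-list peak inside PRR7 (639839 to 639961). Whether they also lie in the PRR7 gene was not examined, so its absence from the PRR9 list rests on the assignment. A peak near GI was named for AT1G22767 in the PRR7, PRR5 and TOC1 lists, and a PRR7 peak near ELF4 for AT2G40081 (score 4.999).

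**Figure D3:**
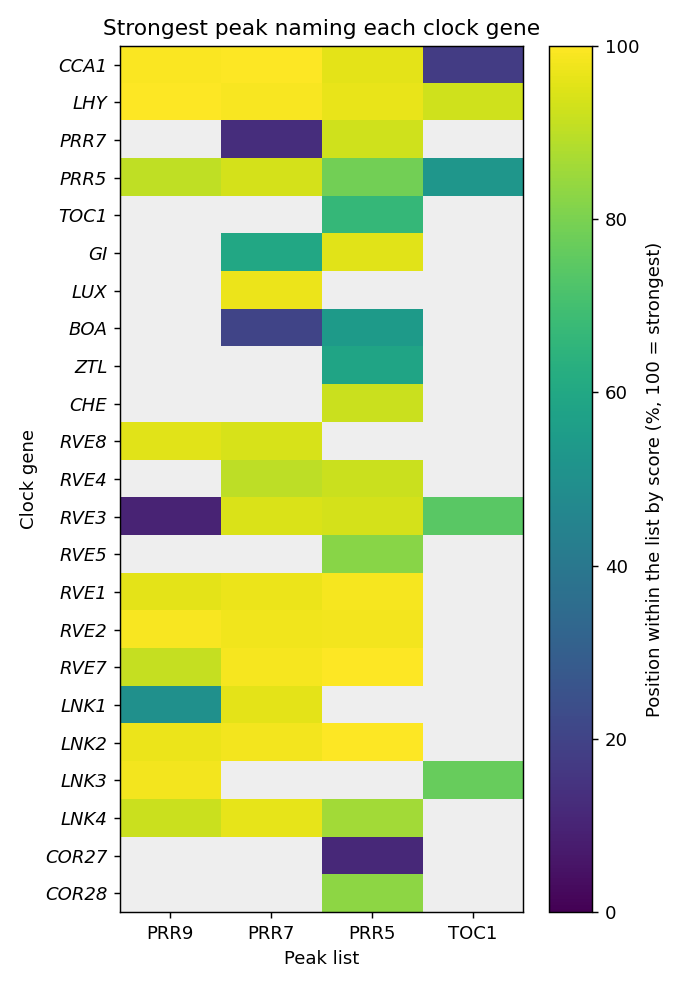
Heat map of the 23 core clock genes named in at least 1 list (vertical axis) in the 4 peak lists (horizontal axis). Color gives the place of the strongest peak of that gene within its own list by score, in percent, with 100 the strongest, and light grey marks genes the list did not name; LHY and CCA1 are colored in all 4 lists.

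The strongest PRR9 peak lay beside PRR9 itself, on chromosome 2 from 19232214 to 19232717 (TAIR10), with a score of 108. It was named for AT2G46787, and peaks of all 3 other lists overlapped it. The tagged line also carries the PRR9 promoter in its transgene. Next came the peaks of LHY (chromosome 1, 37687 to 38163, score 95.8), CCA1 (chromosome 2, 19245244 to 19245750, 74.9) and RVE2 (chromosome 5, 14755415 to 14756142, 61.8). AT2G01023 (60.9), LNK3 (54.0), AGL44 (53.4), AT5G10340 (47.0), LNK2 (37.5) and BBX28 (37.1) completed the first 10. The AT2G01023 and AT5G10340 peaks were overlapped by TOC1 peaks only. The AT2G01023 peak lay near the start of chromosome 2 (9768 to 10177). PRR9 and TOC1 were also the only lists with peaks named for rRNA genes (4 and 2, against 0 for PRR7 and PRR5). Recovery of repeated DNA was not tested for the AT2G01023 and AT5G10340 peaks. RVE1 had 6 PRR9 peaks, and BBX31, CDL1, the rRNA locus AT3G41979 and the pseudogenes AT4G06700 and AT5G31821 had 3 each. The first 10 PRR7 peaks were those of CCA1 (49.3), LHCB1.1, AT1G26790, AT2G46787, AT5G15950, AT1G42420, LHCA1, BBX28, PIF5 and AT2G30766 (36.1). For PRR5 they were those of AT1G26790, AT2G30766, ZFP8, AT3G50665, AT1G60150, AT4G38860, AT3G14205, RVE7, CLC-B and HB4, with scores of 55.6 to 55.2. For TOC1 they were those of RBOHD, an NADPH oxidase gene (19.8), NUDT4, AT2G01023, AT1G32920, AT5G35735, CAF1a, BME3, ZAT10, FC1 and AT1G79245 (12.2). All but AT2G01023 of these 10 TOC1 peaks lay inside the gene.

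Output genes known to follow the clock were also named, and several groups passed in more than 1 list. Photoperiodic flowering genes were named by PRR9 in 3 of 14 cases (CDF2, COL1 and CDF5, adjusted p = 0.000122 by Fisher's exact test), by PRR7 in 8 and by PRR5 in 12 (adjusted p = 1.38e-07 and 4.50e-06, exact). B-box genes were named by PRR9 in 2 of 7 cases (BBX19 and BBX25, adjusted p = 0.00130, Fisher's exact test), by PRR7 in 4 and by PRR5 in 5 (adjusted p = 0.000243 and 0.0174, exact). Cold-response genes were named by PRR9 in 2 of 17 cases (CBF3 and CBF2, adjusted p = 0.00696, exact), by PRR7 in 8, by PRR5 in 15 and by TOC1 in 4 (adjusted p = 7.17e-07, 1.38e-07 and 0.000134, exact). The strongest PRR9 peaks of CBF2 and CBF3 lay close together on chromosome 4 (13016157 to 13016570 and 13019136 to 13019435). The PRR9 call thus rests on a single region, while the test counts the 2 genes as independent. Flavonoid genes were named by PRR9 in 2 of 8 cases (F3H and MYB12, adjusted p = 0.00164, exact), by PRR7 in 2 (adjusted p = 0.0708, exact) and by PRR5 in 6 (adjusted p = 0.00587, exact). Light-harvesting genes, which encode chlorophyll-binding antenna proteins, were named by PRR7 in 15 of 18 cases (odds ratio 124, adjusted p = 1.37e-17, exact) and by PRR5 also in 15 (odds ratio 17.7, adjusted p = 5.12e-07, exact). PRR9 named LHCB1.1 alone among them (adjusted p = 0.125, exact), and TOC1 named 1 (adjusted p = 0.268, exact). Phytochrome-interacting factor and growth genes were named by PRR5 in 12 of 14 cases, led by ATHB2, PIF4, PIL1, PIF5 and PIF6, by PRR7 in 3, by TOC1 in 2 (PIF4 and PIF5) and by PRR9 in 0, which allows a share of up to 23.2%. PRR9 named none of the ABA, photoreceptor and starch genes. PRR5, the longest list, named PHYB, PHOT2, PHOT1, ABF2, ABF3, RAB18, ABI1, CHLH, GBSS1, SEX1 and BAM3 among them. Of these 3 lists, only photoreceptors in PRR7 passed, with 3 of 9 genes (adjusted p = 0.0105, exact), and not with the 279 strongest peaks of each list (1 gene, adjusted p = 0.164, exact). Of the 2 genes whose promoters drive the transgenes, PRR9 and GRP7 (also called CCR2), PRR5 named GRP7 (adjusted p = 0.524, exact). The 14 highly transcribed genes served as a check on unspecific recovery. PRR9 named 0 of them, PRR7 6 (adjusted p = 3.88e-05, exact) and TOC1 2 (adjusted p = 0.0245, exact). PRR5 named 11, led by RBCS2B, RCA, UBQ10, RBCS3B and CA1 (adjusted p = 4.90e-05, exact). The odds ratios were 18.5 for PRR7, 12.9 for PRR5 and 14.2 for TOC1, against 24.9, 5.16 and 15.9 for clock genes. Unspecific recovery therefore stays open for gene lists enriched in PRR7, PRR5 and TOC1. The check cannot decide it for PRR9 either. Its 0 of 14 allows a share of up to 23.2%, while PRR9 named only 0.455% of all genes. The TOC1 call was lost with summits from 1000, 500 or 3000 bp upstream to 200 bp downstream (adjusted p = 0.120, 0.0911 and 0.154, exact). With the 279 strongest peaks or the stronger 50%, 0 members remained named. Many of these encode photosynthesis proteins. The 11 constitutive genes, of which PRR5 named ACT7, UBQ10, GAPC1 and TUB2, gave no pair past the threshold (smallest adjusted p = 0.116, exact). ACT2, another member, was not counted as named. Peaks of PRR9 (score 5.38) and PRR5 (16.1) were named for AT3G18779, whose nearest matched gene is ACT2. In all, 25 of the 52 pairs passed the threshold of 0.05. With the stronger 50% of each list the PRR9 calls of photoperiodic flowering (adjusted p = 0.0653, exact) and flavonoid genes (adjusted p = 1, exact) were lost. With the 279 strongest peaks, PRR5 named 0 light-harvesting, flavonoid and highly transcribed genes. With summits from 1000 bp upstream to 200 bp downstream, the calls of cold-response genes in TOC1 (adjusted p = 0.140, exact) and of growth genes in PRR7 (adjusted p = 0.0892, exact) were lost.

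Sites that PRR9 shared were stronger sites of PRR7 and PRR5. PRR7 peaks overlapped by PRR9 peaks had a median score of 13.2 and the rest 4.46, a difference of 8.71 (two-sided permutation p = 1e-05, the smallest possible, adjusted p = 2.4e-05 over 12 tests). PRR5 peaks overlapped by PRR9 peaks had a median score of 31.9 against 8.08 (permutation p = 1e-05, adjusted p = 2.4e-05). TOC1 peaks did not differ past the threshold by PRR9 overlap (medians 4.31 and 3.88, permutation p = 0.514, adjusted p = 0.616). Within the PRR9 list, peaks overlapped by TOC1 had a median score of 9.30 against 5.78 (permutation p = 0.000140, adjusted p = 0.000280). For PRR7 overlap the medians were 6.68 and 5.62 (permutation p = 0.0140, adjusted p = 0.0241), and for PRR5 overlap 6.66 and 5.65 (permutation p = 0.0179, adjusted p = 0.0269). Without chloroplast and gene-poor peaks, which left 151 of 279, these 3 differences were 2.79, 0.867 and 0.676 for TOC1, PRR7 and PRR5, against 3.52, 1.06 and 1.02 before. They no longer passed (permutation adjusted p = 0.0675, 0.659 and 0.680).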

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

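The tests in this part were chosen after the peak lists had been seen. Signal in data outside the main measurement was found on the chloroplast chromosome, which the nuclear comparisons leave out: 114 PRR9 peaks (40.9% of the list, interval 35.0 to 46.9) and 7 TOC1 peaks (1.45%, 0.583 to 2.96).

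The chloroplast PRR9 peaks covered 42314 bp with a median width of 218.5 bp, and their median score was 5.57. The 7 TOC1 chloroplast peaks all lay in PRR9 chloroplast peaks, against 2.85 expected from random placement (one-sided permutation p = 0.00210). Placements could also fall in a stretch of 27773 bp, from 83880 to 111654, that held no peak of either list. If peaks could not be called in that stretch, the expected value is too low and the p-value too small. Against a recovery bias of plastid DNA common to separate experiments, 0 of 1344 PRR7 and 0 of 9036 PRR5 peaks lay on the chloroplast chromosome. Whether chloroplast reads or peaks were removed before those lists were deposited is not given in the sources used here. The bias therefore stays open. The control immunoprecipitation is not named for the PRR9 list in the description sheet, and no biological explanation was tested.

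Of the 165 nuclear PRR9 peaks, 34 were overlapped by no other list. Of these, 16 (47.1%) lay in gene-poor windows or were named for rRNA genes or pseudogenes, against 3 of the 131 shared peaks (2.29%, odds ratio 37.9, two-sided Fisher's exact p = 2.18e-10). Recovery of repeated DNA is a candidate explanation for those 16, and it leaves the other 18 open. The 18 include the peak of the ncRNA locus AT3G41761 (chromosome 3, 14195875 to 14196129), close to that of the rRNA locus AT3G41768 (14197272 to 14197479). They also include peaks of AT2G46787, RVE1, BBX31, CDL1 and AT1G13605, loci that had a shared PRR9 peak too. The unshared peaks differed from the shared ones by -0.982 in median score (5.69 against 6.68, permutation p = 0.309), so whether they lie closer to the calling threshold cannot be told apart from chance at this number of peaks. Binding by PRR9 alone, or at zeitgeber time 4 alone, was not tested, since protein and time changed together.

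PRR5 peaks overlapped 144 of the 224 TOC1 peaks inside genes (64.3%, interval 57.6 to 70.6), against 2.84% in random placements, which argues against chance peaks. Overlap with all 3 lists was lower inside genes than upstream or over a gene start. It was 64.3% against 88.2% for PRR5, 8.48% against 44.9% for PRR7 and 1.34% against 12.8% for PRR9. The two-sided Fisher's exact p-values were 1.27e-08, 1.16e-17 and 2.57e-06 (adjusted p = 1.90e-08, 3.47e-17 and 2.57e-06 over 3 lists). Taken from the PRR5 list, TOC1 peaks overlapped 4.67% of PRR5 peaks inside genes and 2.999% of those upstream or over a start (odds ratio 1.58, two-sided Fisher's exact p = 0.000645, adjusted p = 0.000645). PRR7 and PRR9 peaks went the other way, with 4.86% against 16.8% and 0.246% against 1.91%. Their odds ratios were 0.252 and 0.127 (two-sided Fisher's exact adjusted p = 1.34e-48 and 1.73e-09). None of 23 constitutive or highly transcribed genes carried a TOC1 peak inside the gene, which allows up to 14.8% against 0.481% of all genes (Fisher's exact p = 1). Unspecific recovery of strongly transcribed genes therefore cannot be told apart with so few genes. The count also depends on the category and the members chosen. UBQ10, a member, had a TOC1 peak over its end, 1904 bp from its start. UBQ11, not a member, had a peak inside it (score 9.70). A biological difference between TOC1 or its collection time and the other lists stays open, untested.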

How the results depend on the processing

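Placements by shift or at named starts (shifting each peak by 5 to 50 kb, and moving it to starts of named genes) and the joint gene assignment per overlapping site were chosen after seeing the data; the others were planned. All 42 alternatives of peak overlap and all 42 of shared genes kept their direction and stayed past the threshold. Of 313 alternative values, 278 kept direction and side of the threshold or stayed within the counting interval. Genes named in all 4 lists numbered 15 and 9 with summits from 1000 and 500 bp upstream to 200 bp downstream. They numbered 6 with the 279 strongest peaks and 6 with the stronger 50%. Score differences of PRR9 peaks without chloroplast and gene-poor peaks were 0.867 (PRR7), 0.676 (PRR5) and 2.79 (TOC1), no longer past the threshold; that of PRR7 peaks by PRR5 overlap passed at 1.39 with summits within 250 bp. The cause was not tested. Summits near the start were 61.4% (PRR9) and 62.5% (PRR7) in the stronger 50%. By construction, the 500 bp window gave 43.6%, 47.2%, 42.5% and 24.7%, and the 3000 bp window 78.2%, 79.5%, 67.1% and 44.0%, for PRR9, PRR7, PRR5 and TOC1. Odds ratios of 0 replaced enrichment with the 279 strongest peaks for light harvesting, flavonoid and highly transcribed genes in PRR5 and highly transcribed genes in TOC1, and with the stronger 50% for flavonoid genes in PRR9 and highly transcribed genes in TOC1, where 0 members remained named. A further 11 alternative values kept the direction but lost the threshold, for growth and photoreceptor genes in PRR7, cold and highly transcribed genes in TOC1 and photoperiodic flowering genes in PRR9. Uniform placement and the deposited gene assignment became the main settings. Motif alternatives, another strength column, and the planned placement test of summit positions were not run. No paired analysis was possible because each group held 1 library. Read depth was not examined, which limits any statement on sites absent from a list.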

Other observations

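Gene families were matched by symbol after the lists had been seen, in 14 families and 56 two-sided Fisher's exact tests, of which 20 passed an adjusted 0.05. B-box and CONSTANS-like genes, zinc-finger regulators of light and flowering responses, were the family most often named by PRR9, with 7 of 30 members (odds ratio 70.4, Fisher's exact p = 6.40e-11, adjusted p = 1.20e-09). PRR7 named 13 of them, PRR5 25 and TOC1 4 (Fisher's exact adjusted p = 8.68e-10, 9.55e-11 and 0.00172). ERF and DREB transcription factor genes were named in 2 of 39 cases by PRR9, 9 by PRR7, 24 by PRR5 and 6 by TOC1 (Fisher's exact adjusted p = 0.0383, 0.000124, 1.80e-06 and 5.38e-05). The 2 named by PRR9 were again the neighbours CBF3 and CBF2, so that call also rests on a single region. ABC transporter genes were named in 4 of 127 cases by PRR9, ABCF5, ABCF2, ABCG22 and ABCI15 (Fisher's exact p = 0.00275, adjusted p = 0.0103).

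Of the auxin-related families, PRR5 named SAUR genes in 36 of 80 cases and Aux/IAA genes in 17 of 32 (odds ratios 2.89 and 4.003, Fisher's exact adjusted p = 5.38e-05 and 0.000643). PRR7 named 6 SAUR and 3 Aux/IAA genes (Fisher's exact adjusted p = 0.269 and 0.268), and PRR9 and TOC1 named 0 members of both. ZAT zinc-finger genes were named in 8 of 9 cases by PRR5 and 3 by TOC1, ZAT10, ZAT6 and ZAT12 (Fisher's exact adjusted p = 0.000255 and 0.000643). WRKY genes were named in 32 of 72 cases by PRR5 (Fisher's exact adjusted p = 0.000165) and 2 by TOC1, WRKY40 and WRKY48 (adjusted p = 0.342, exact). Of the 20 strongest nuclear TOC1 peaks, 18 lay inside genes, among them RBOHD, ZAT10, CAF1a and WRKY40. Over the whole list, the median score was 4.201 inside genes and 3.66 upstream or over a gene start, a difference of 0.539 that did not pass the threshold (two-sided permutation p = 0.262).

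The other family tests that passed were MYB genes in PRR7 and PRR5 (Fisher's exact adjusted p = 0.00172 and 0.0114), calcium-dependent and CIPK kinase genes in PRR7 (0.00207), bZIP and NAC genes in PRR5 (0.0114 and 0.0304) and JAZ genes in PRR7 (0.0304).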
